A study of Homo sapiens with 6 samples.

How the data were processed

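RNA of CD34-positive bone marrow cells of 3 donors was sequenced in bulk, with 1 untreated and 1 interferon gamma library per donor. Per the submitters' processing notes, Trimmomatic 0.39, fastp 0.23.2 and STAR 2.7.9a were used with genome build hg38, with no role or order given. The gene counter, the annotation and any filter on genes are not given in the sources used here. The authors deposited 1 table of RPKM values (reads scaled by gene length and by the reads of the library), in which 6 columns were used and 0 were not. Whether library sizes were rescaled beyond that is not given in the sources used here. RPKM divides by the total of each library, so a few very abundant induced genes lower the values of all others, and 2 rescalings of the libraries were tried for this reason.

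Column names show the group and a donor code that matches no sample title, so each column was assigned to its group only, and the pairing by donor was read from the code that the 2 columns of a donor share. The design written before the data were examined took the pairing from the titles, so this departs from it. The deviations from the group means correlated at 0.94, 0.91 and 0.90 between the 2 libraries of a donor, and at -0.61 to -0.31 between libraries of different donors. Deviations cancel out over the libraries of a group, so positive values within donors force negative ones between donors. The libraries of a group come from separate donors.

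The table held 14244 rows. In 20 rows a spreadsheet had turned the gene name into a date, and these were dropped. Of the 14224 symbols left, 13414 (94.3%) matched GENCODE release 29 on GRCh38, from which coordinates were taken, and 810 did not, among them C1orf186. Then 18 rows of sex-linked genes were left out of every test. Strand use in the authors' counting is not given in the sources used here, so reads of overlapping genes cannot be told apart.

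Depth was read from the steps between low values, since 1 read is worth a fixed amount per gene and library. Of 703 genes with a mean under 0.3 RPKM, 666 (94.7%) came out as whole reads within 0.02 of a read. With 14 single-exon genes of known length, the depths were estimated at 15200000 and 12800000 reads for donor A (interferon gamma and untreated), 14700000 and 18200000 for donor B and 15300000 and 10700000 for donor C. These are rough, since the estimate from single genes for 1 library had quartiles of 14600000 and 31600000 reads. The ratios between libraries do not depend on gene length.

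Genes with a mean of at least 0.5 RPKM over the 6 libraries were tested, which kept 12991. limma 3.58.1 in R 4.3.3 was fitted to log2(RPKM + 1) with donor as a fixed block and treatment, and eBayes with an intensity trend moderated the variances (2 residual and 3.68 prior degrees of freedom). All log2 changes are on that scale, which understates changes of genes near 1 RPKM. Benjamini-Hochberg adjusted p values under 0.05 were called. Donor is a block because the series' design text says that the cells of every donor went to both groups. For CD38 an exact two-sided sign-flip permutation test over donors was added. The 30 gene lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, whose directional p asks whether the genes of a list move one way on balance and whose mixed p asks whether they change at all. Benjamini-Hochberg adjustment ran over the 30 lists.

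The genes named were fixed by a rule before the data were examined. It took 10 preset genes (among them CD38, IRF1, CIITA, CD274, CD33, IL3RA, CD34, MKI67 and MYC), the 12 largest rises and 8 largest falls among called genes with the same sign in all donors, and up to 4 called members per list with the smallest p, or 2 members where none was called. A fixed set of genes known to vary by gene copy between people, which did not cover the tryptases, was left out of it. Genes named outside the rule are said to be so, and some genes that the rule takes are not reported here.

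The fit was tested on simulated data for this comparison, with 12991 genes, 200 of them changed, in 5 runs. It recovered 62.0% of changes of 0.5 on the log2 scale, 96.3% of changes of 1 and 97.9% of changes of 2. Among calls of genes that were changed, 100% had the right sign. False calls made up 8.32%, somewhat above the 5% aimed at. Of 30 unchanged lists 0.2 were called on average, but the simulated noise was independent between genes. The runs therefore cannot vouch for the preset correlation of 0.01 where the members of a list move together. The correlation estimated from the data reached 0.81 in a called list, that of erythroid markers. A list shifted by 0.5 was called in 5 of 5 runs at the preset correlation and in 0 of 5 with an estimated one, so a list that misses the threshold in the second test is weak evidence against a shift.

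Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at 5 RPKM, no donor block, donor as a random effect, quantile normalization, scaling to equal medians, no intensity trend, robust eBayes, leaving out each donor, an adjusted p under 0.1, a minimum change of 1, and the other list tests. A test for raw counts was planned in case counts were deposited, and it was not run because the values are RPKM. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.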

Results

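Gene expression was measured by bulk RNA sequencing in CD34-positive bone marrow cells from 3 donors with relapsed acute myeloid leukaemia (AML). CD34 is a surface marker of haematopoietic stem and progenitor cells and is used to enrich immature leukaemic cells. Part of the cells of each donor was kept overnight with interferon gamma at 10 ng/ml and part with vehicle, here called untreated, which gave 3 libraries per group and 6 libraries in all. Interferon gamma is a cytokine of activated T and NK cells that acts through the JAK-STAT pathway. The donors are called A, B and C, and the letters have no meaning. Values were deposited as RPKM, and the depth estimated from the steps between low values ranged from about 10700000 to 18200000 reads per library. A transcript of 2 kb at 1 RPKM then stands for about 21.4 to 36.3 reads.

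The first comparison asked whether interferon gamma raised CD38, the antigen of the T cell engager named in the study's title. CD38, a surface glycohydrolase that consumes NAD, rose in each of 3 donors, from 12.5 ± 6.99 to 96.9 ± 80.3 RPKM (SD, n = 3). Within donors the RPKM value rose 6.24-fold in donor A, from 5.74 to 35.8. It rose 9.54-fold in donor B, from 19.7 to 188, and 5.62-fold in donor C, from 11.9 to 67.0. The mean ratio was 7.13 ± 2.11 (SD, n = 3). On the log2(RPKM + 1) scale the change was 2.68 with an SE of 0.17 and a 95% interval of 2.27 to 3.09 (limma adjusted p = 0.00271). CD38 ranked number 34 by size of rise among 12991 genes. The gene (ENSG00000004468) is protein coding and lies on chromosome 4 at 15778275 to 15853230, plus strand, in GRCh38. An exact two-sided sign-flip permutation test over the 3 donor differences gave p = 0.25, the smallest p that 3 donors allow. The donors started from different levels, and without donor as a block the limma adjusted p was 0.999877, at the same log2 change of 2.68. The unadjusted limma p of CD38 in that fit was 0.00726.

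**Figure D1:**
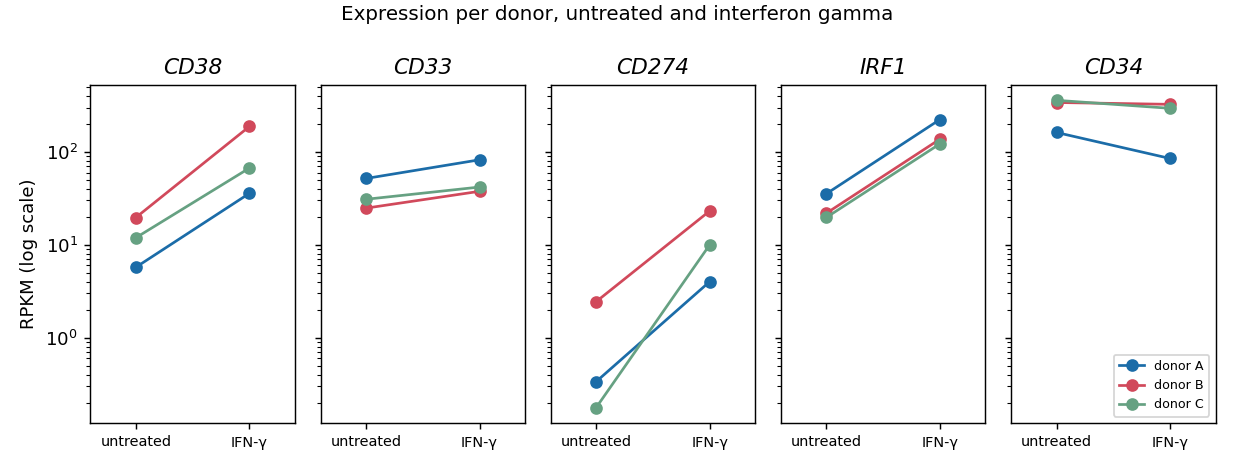
RPKM (log axis) of CD38, CD33, CD274, IRF1 and CD34 in the untreated and the interferon gamma library of each donor, with 1 line per donor joining its 2 groups. CD38 rose 6.24-fold, 9.54-fold and 5.62-fold in donors A, B and C, while the mean of CD34 was 287 RPKM untreated and 235 RPKM with interferon gamma.

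The second comparison covered every gene. The largest rises belonged to chemokines that attract T cells and to guanylate-binding proteins, which are interferon-induced GTPases of cell defence. CXCL9 rose by 7.91 on the log2 scale, CXCL10 by 7.14, GBP1 by 6.63, GBP5 by 5.05 and CXCL11 by 4.90. HAPLN3 rose by 4.39, SECTM1 by 4.23, the transcription factor BATF2 by 4.13, the tryptophanyl-tRNA synthetase WARS by 3.97, RARRES3 by 3.94 and the JAK-STAT inhibitor SOCS1 by 3.93. GBP1P1 rose by 5.01, but it is a pseudogene of GBP1 and may share reads with it, so its value is uncertain. The interferon-induced transcription factor IRF1 rose by 2.59 (adjusted p = 0.000206), from 25.7 ± 8.54 to 161 ± 54.5 RPKM (SD, n = 3). Falls were smaller. The gelatinase MMP9 fell by 1.99, from 10.8 ± 8.19 to 2.18 ± 2.71 RPKM. EEF1A2 fell by 1.26, elastin (ELN) by 1.14, the sulfatase SULF2 by 1.14, the chemokine-like PROK2 by 1.12, C1orf186 by 1.06, CD93 by 1.03 and the gelatinase MMP2 by 1.01.

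In all, 576 of the 12991 genes passed an adjusted p of 0.05, of which 411 rose and 165 fell. All 576 had the same sign in the 3 donors, which a test with donor as a block favours. Among them 203 rose and 11 fell by at least 1 on the log2 scale. The median rise was 0.99, the median fall was -0.63, and the median change of all genes tested was -0.01. Without donor as a block, limma called 0 genes, with 290 at an unadjusted p under 0.05 against 3323 with the block. Quantile normalization gave 345 risen and 238 fallen genes. Leaving out donor A left 322 calls and leaving out donor C left 263, of which 271 and 232 were among the 576. Without donor C the calls of CXCL9 (adjusted p = 0.108), GBP5 (0.0553), ELN (0.129), PROK2 (0.0525) and MMP2 (0.0908) were lost, and without donor A that of EEF1A2 (0.0581). A pseudocount of 5 ended the calls of CXCL9 (0.0860), CXCL11 (0.0532), EEF1A2 (0.0551) and ELN (0.0868), and robust eBayes those of CXCL9 (0.0856) and ELN (0.0531).

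**Figure D2:**
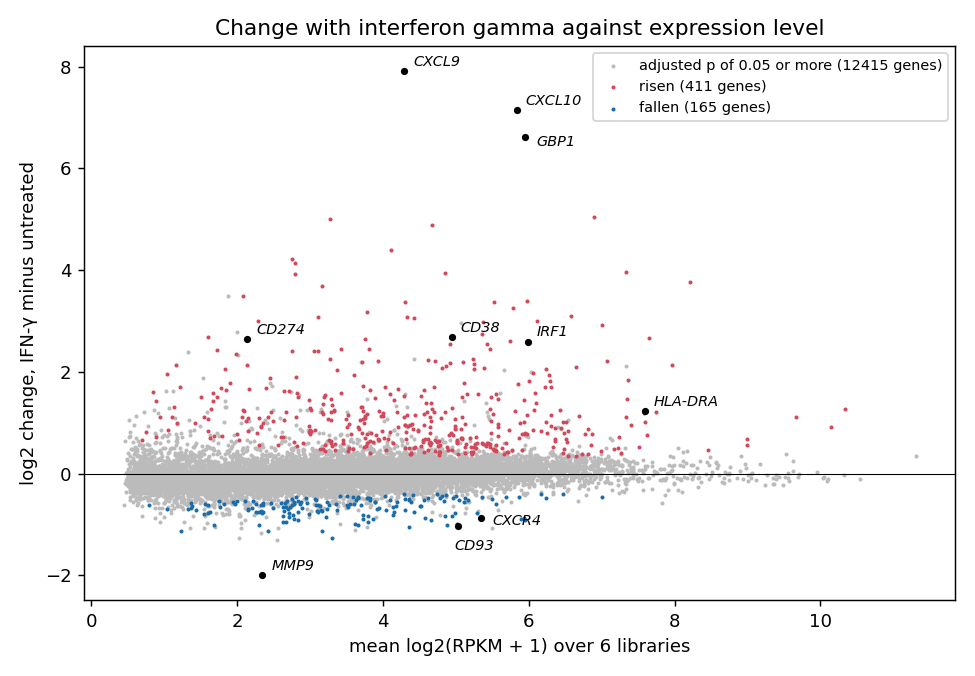
Log2 change with interferon gamma (vertical axis) against the mean log2(RPKM + 1) over 6 libraries (horizontal axis), 1 point per gene tested, with risen genes in red, fallen genes in blue, others in grey and labelled genes in black. The 411 risen genes reach a change of 7.91 (CXCL9), while the largest fall among the 165 fallen genes is -1.99 (MMP9).

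Gene lists chosen before the data were examined were tested next, each against all other genes, and 20 of the 30 lists passed. None of the 20 passed when the correlation between genes was estimated from the data, and that p is given beside each. In the interferon gamma response list 26 of 30 members rose and 0 fell (30 rose adjusted over the list alone), with a median log2 change of 2.86. Its camera adjusted p was 3.84e-31, against an adjusted p = 0.235 with an estimated correlation. Besides IRF1, GBP2 rose by 3.39, ANKRD22 by 3.50 and LAP3 by 2.93. Among type I interferon response genes, 20 of 31 rose and 0 fell (30 rose adjusted over the list alone), with a median of 1.71 (camera adjusted p = 4.55e-23; adjusted p = 0.375 with an estimated correlation). IFIT2 rose by 3.06, RSAD2 by 2.19, CMPK2 by 1.65 and USP18 by 1.51. RSAD2 and CMPK2 overlap at their ends on opposite strands, and reads of the overlap cannot be told apart. With a pseudocount of 5 USP18 was at 0.94 and lost its call (limma adjusted p = 0.0814). Restriction factors and guanylate-binding proteins rose in 21 of 28 cases (27 adjusted over the list alone), with a median of 1.63 (camera adjusted p = 2.81e-24; adjusted p = 0.235 with an estimated correlation), and the apolipoproteins APOL6 and APOL2 rose by 2.99 and 2.07. In the JAK-STAT list 11 of 23 rose and 0 fell, or 14 and 1 adjusted over the list alone. Its median was 0.44 (camera adjusted p = 6.54e-06; adjusted p = 0.267 with an estimated correlation), and STAT2 rose by 2.06.

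Antigen presentation genes rose in both HLA classes. For class I, 16 of 20 rose and 0 fell (19 rose adjusted over the list alone), with a median of 1.23 (camera adjusted p = 9.61e-19; adjusted p = 0.375 with an estimated correlation). The peptide transporter genes TAP1 and TAP2 rose by 3.37 and 1.58, and the immunoproteasome genes PSMB9 and PSMB10 by 2.45 and 1.45. TAP1 lies within the bounds of PSMB9 on the opposite strand. Strand use is not given, so the rises of TAP1 and PSMB9 may not be separate. For class II, 12 of 16 rose and 0 fell (15 rose adjusted over the list alone), with a median of 1.14 (camera adjusted p = 1.08e-12; adjusted p = 0.321 with an estimated correlation). CIITA, the master regulator of class II genes, rose by 1.16 (adjusted p = 0.0211), from 53.6 ± 16.2 to 118 ± 0.389 RPKM. HLA-DRA rose by 1.23, HLA-DPA1 by 1.23, HLA-DPB1 by 1.13 and HLA-DMA by 0.77. HLA genes are near copies of each other and vary between people, so reads may be split among them. HLA-DPA1 and HLA-DPB1 also overlap on opposite strands, and reads of the overlap cannot be told apart. Without donor C the calls of CIITA (adjusted p = 0.0896), HLA-DRA (0.0597), HLA-DPA1 (0.0536), HLA-DPB1 (0.0861) and HLA-DMA (0.0609) were lost, and without donor A those of HLA-DPB1 (0.0547) and HLA-DMA (0.0544).

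Genes through which cells meet T cells moved in part. The checkpoint ligand CD274 (PD-L1) rose by 2.65 (adjusted p = 0.00798), from 0.988 ± 1.27 to 12.4 ± 9.80 RPKM. Among co-signalling and checkpoint ligands 4 of 17 rose and 0 fell (6 rose adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.00198; adjusted p = 0.321 with an estimated correlation). CEACAM1 rose by 1.79, the costimulatory ligand CD86 by 0.94 and LGALS9 by 0.63. The call of CD86 was lost without donor A (adjusted p = 0.109) and that of LGALS9 without donor C (adjusted p = 0.132). Chemokines and cytokines rose in 5 of 23 cases and fell in 0 (10 rose adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.00334; adjusted p = 0.321 with an estimated correlation). In the cell death list 12 of 25 rose and 0 fell (14 rose adjusted over the list alone), with a median of 0.52 (camera adjusted p = 4.29e-08; adjusted p = 0.235 with an estimated correlation). TNFSF10, the death ligand TRAIL, rose by 2.09, the death receptor FAS by 1.35, PMAIP1 by 1.14 and CASP4 by 1.02. Of 18 complement and Fc receptor genes 6 rose and 0 fell, or 6 and 1 adjusted over the list alone. Their median was 0.50 (camera adjusted p = 0.00353; adjusted p = 0.377 with an estimated correlation), and the complement inhibitor SERPING1 rose by 3.00.

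The AML surface antigens did not move as a group. Of 22 tested, 5 rose and 4 fell (6 and 7 adjusted over the list alone). The median change was -0.13, the mean was 0.20, and the camera test pointed down with an adjusted p of 0.823. On the log2(RPKM + 1) scale CD38 rose more than each of the other 21 antigens on average over donors. It rose more than 20 of them in every donor, though these differences were not tested. The exception was the Fc receptor FCGR1A, which rose by 2.43 and may share reads with its near copies. That scale understates its rise, since it started under 1 RPKM. FCGR1A went from 0.572 to 10.4, 0.0253 to 2.57 and 0.817 to 10.2 RPKM in donors A, B and C. These are larger ratios than those of CD38 in every donor, and ratios of the other antigens were not compared. IL2RA rose by 0.86 and CD33 by 0.56 (adjusted p = 0.0215), from 35.8 ± 14.1 to 53.9 ± 24.6 RPKM. The chemokine receptor CXCR4, which holds stem cells in the marrow, fell by 0.87. ADGRE2, CLEC12A and CD44, named here after their values were seen, fell by 0.63, 0.62 and 0.46. IL3RA, which encodes CD123, had a log2 change of 0.24 with a 95% interval of -0.04 to 0.52 and did not pass (adjusted p = 0.252). The call of CD33 was lost without donor A (adjusted p = 0.114) and without donor C (0.0532), as were those of ADGRE2 (0.0672 and 0.0631), CLEC12A (0.0648 and 0.138) and CD44 (0.117 and 0.182), and CLEC12A was also lost without donor B (0.0517). In the tryptophan and NAD metabolism list, which also holds CD38 and WARS, 8 of 22 rose and 0 fell (10 rose adjusted over the list alone). Its median was 0.22 (camera adjusted p = 0.000131; adjusted p = 0.375 with an estimated correlation), and NAMPT, a rate-limiting enzyme of NAD salvage, rose by 1.37, while adenosine deaminase (ADA) rose by 0.79.

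Few stem cell and lineage markers passed. CD34 itself had 287 ± 109 RPKM untreated and 235 ± 131 RPKM with interferon gamma (SD, n = 3), a log2 change of -0.42 that did not pass (adjusted p = 0.189). The donor changes of CD34 were -0.92, -0.07 and -0.29, so donor A carried much of it. Of the 17 genes of the LSC17 score, a published stemness signature of AML, 0 passed over all genes and 0 adjusted over the list alone. Their median was -0.20 (camera adjusted p = 0.0231; adjusted p = 0.377 with an estimated correlation), with SMIM24 at -0.74 and DNMT3B at 0.64. SMIM24 passed with donor as a random effect (adjusted p = 0.0337). Likewise 0 of 23 stem and progenitor factors passed either way, with a median of -0.23 (camera adjusted p = 0.0107; adjusted p = 0.414 with an estimated correlation), KIT at -0.72 and CRHBP at -0.52. Without donor B, KIT passed at -0.98 (adjusted p = 0.00629). Among granule proteins of myeloid precursors 1 of 13 fell (8 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 0.000113; adjusted p = 0.457 with an estimated correlation). That gene was the protease CTSG, which fell by 0.82, a call lost without donor A (adjusted p = 0.0781) or donor C (0.0861). Erythroid markers had 0 of 13 past the threshold either way and a median of 0.34 (camera adjusted p = 0.0237; adjusted p = 0.670 with an estimated correlation), with HBD at 0.75 and AHSP at 0.63. That camera adjusted p was 2.49e-05 without donor A and 0.770 without donor C, and the call was also lost with a pseudocount of 0.1 (0.0553) and a filter at 5 RPKM (0.244). HBD, at 0.101 RPKM or less in donor A, passed without that donor at 1.20 (adjusted p = 0.00647), and AHSP passed with a pseudocount of 0.1 at 1.04 (0.0431). Among 9 megakaryocyte markers SELP alone fell, by 0.60 (2 fell adjusted over the list alone), and the median was -0.15 (camera adjusted p = 0.0418; adjusted p = 0.396 with an estimated correlation). The camera call of that list was lost without donor A (adjusted p = 0.106) or donor B (0.0518), with a pseudocount of 5 (0.135), a filter at 5 RPKM (0.387) and quantile normalization (0.102). The call of SELP was lost without any 1 of the donors (0.169, 0.126 and 0.0865).

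Markers of other cells that a CD34 enrichment can carry along did not pass as lists, except that dendritic cell markers did under quantile normalization (camera adjusted p = 0.0226). Of 21 monocyte and macrophage markers 1 rose, the transcription factor CEBPB by 1.18 (1 adjusted over the list alone), at a median of -0.01, a mean of 0.04 and a camera adjusted p of 0.923. Of 9 T and NK cell markers 1 fell, IL7R by 0.68 (1 rose and 3 fell adjusted over the list alone), at a median of -0.15 and a camera adjusted p of 0.430. The IL7R call was lost without any 1 of the donors (0.0955, 0.0570 and 0.0877). Of 7 B and plasma cell markers 0 passed either way, at a median of -0.11, a mean of 0.01 and a camera adjusted p of 0.671, with CD79A at -0.32 and MZB1 at 0.64. Of 4 stromal and endothelial markers 0 passed (1 fell adjusted over the list alone), at a median of -0.08 and a camera adjusted p of 0.572, with PECAM1 at -0.53 and PDGFRB at 0.43. PECAM1 passed without donor A at -0.69 (adjusted p = 0.0426), with donor as a random effect (0.0272) and under quantile normalization (0.0345). Of 8 dendritic cell markers LAMP3 rose from a mean of 0.784 to 4.57 RPKM (adjusted p = 0.0156) and CCR7 rose by 1.11 on the log2 scale (4 rose and 1 fell adjusted over the list alone), at a median of 0.38 and a camera adjusted p of 0.0748. Without donor C both calls were lost (0.0609 and 0.155), and without donor B that of CCR7 (0.0573). With a pseudocount of 5 LAMP3 was at 0.66 and CCR7 at 0.65, and both calls were lost (0.0876 and 0.108).

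The lists of growth, mitochondrial, sterol, stress, NF-kB and housekeeping genes had medians between -0.01 and 0.39, and some of them passed. MYC had a log2 change of -0.04 (adjusted p = 0.738) and the proliferation marker MKI67 one of -0.23 (adjusted p = 0.352). Of 26 cell cycle genes 0 passed either way, at a median of 0.04 and a camera adjusted p of 0.266, with CCNB1 at 0.24 and CCND2 at -0.25. Under quantile normalization CCND2 passed at -0.39 (adjusted p = 0.0448). Donor medians of that list were 0.35, -0.29 and 0.18, and without donor B its camera adjusted p was 1.34e-06. In the list of MYC targets and ribosome biogenesis 1 of 24 rose, the chaperonin HSPE1 by 0.63 (1 adjusted over the list alone), at a median of 0.18 (camera adjusted p = 0.000137; adjusted p = 0.569 with an estimated correlation). Oxidative phosphorylation had 1 of 23 risen, COX5B by 0.35 (9 adjusted over the list alone), and a median of 0.22 (camera adjusted p = 1.51e-06; adjusted p = 0.391 with an estimated correlation). Both of these camera calls were lost under quantile normalization (adjusted p = 0.101 and 0.0952). Cholesterol synthesis had 0 of 25 past the threshold either way and a median of 0.21 (camera adjusted p = 0.00144; adjusted p = 0.428 with an estimated correlation), with FDPS at 0.31 and IDI1 at 0.41. FDPS passed with donor as a random effect (adjusted p = 0.0443). Among 17 genes of endoplasmic reticulum stress HERPUD1, ATF5 and DDIT3 rose, by 0.66, 0.67 and 0.38 (7 adjusted over the list alone), at a median of 0.39 (camera adjusted p = 6.60e-05; adjusted p = 0.414 with an estimated correlation). Of 21 immediate early and heat shock genes ATF3 rose by 1.09, HSPA8 by 0.57, HSP90AA1 by 0.46 and HSPH1 by 0.45 (4 rose and 1 fell adjusted over the list alone). The median of that list was -0.01, its mean 0.05 and its camera adjusted p 0.572. The NF-kB list had 2 of 18 risen, SOD2 by 1.59 and TNFAIP2 by 0.94 (4 rose and 2 fell adjusted over the list alone), a median of 0.00 and a camera adjusted p of 0.549. Of 16 reference housekeeping genes 0 passed (2 rose adjusted over the list alone), at a median of 0.02 and a camera adjusted p of 0.374, with SDHA at 0.34, which passed without donor B at 0.39 (adjusted p = 0.0421) and with donor as a random effect (0.0436). The calls of HSPE1 (0.139 and 0.123), COX5B (0.233 and 0.180), HERPUD1 (0.129 and 0.115), ATF5 (0.133 and 0.0628), DDIT3 (0.223 and 0.140), HSPA8 (0.0634 and 0.193), HSPH1 (0.157 and 0.129), HSP90AA1 (0.128 and 0.218) and TNFAIP2 (0.128 and 0.155) were lost without donor A and without donor C. Those of ATF5 (0.0664), COX5B (0.0529) and DDIT3 (0.0690) were also lost without donor B. Under quantile normalization COX5B was at 0.15 and lost its call (adjusted p = 0.262). HSP90AA1 (0.208), HSPA8 (0.132), HSPH1 (0.0737), DDIT3 (0.0607), HSPE1 (0.0584) and TNFAIP2 (0.0530) lost theirs there too. Scaling to equal medians ended the calls of COX5B (0.0552), DDIT3 (0.0516) and ATF5 (0.0503).

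**Figure D3:**
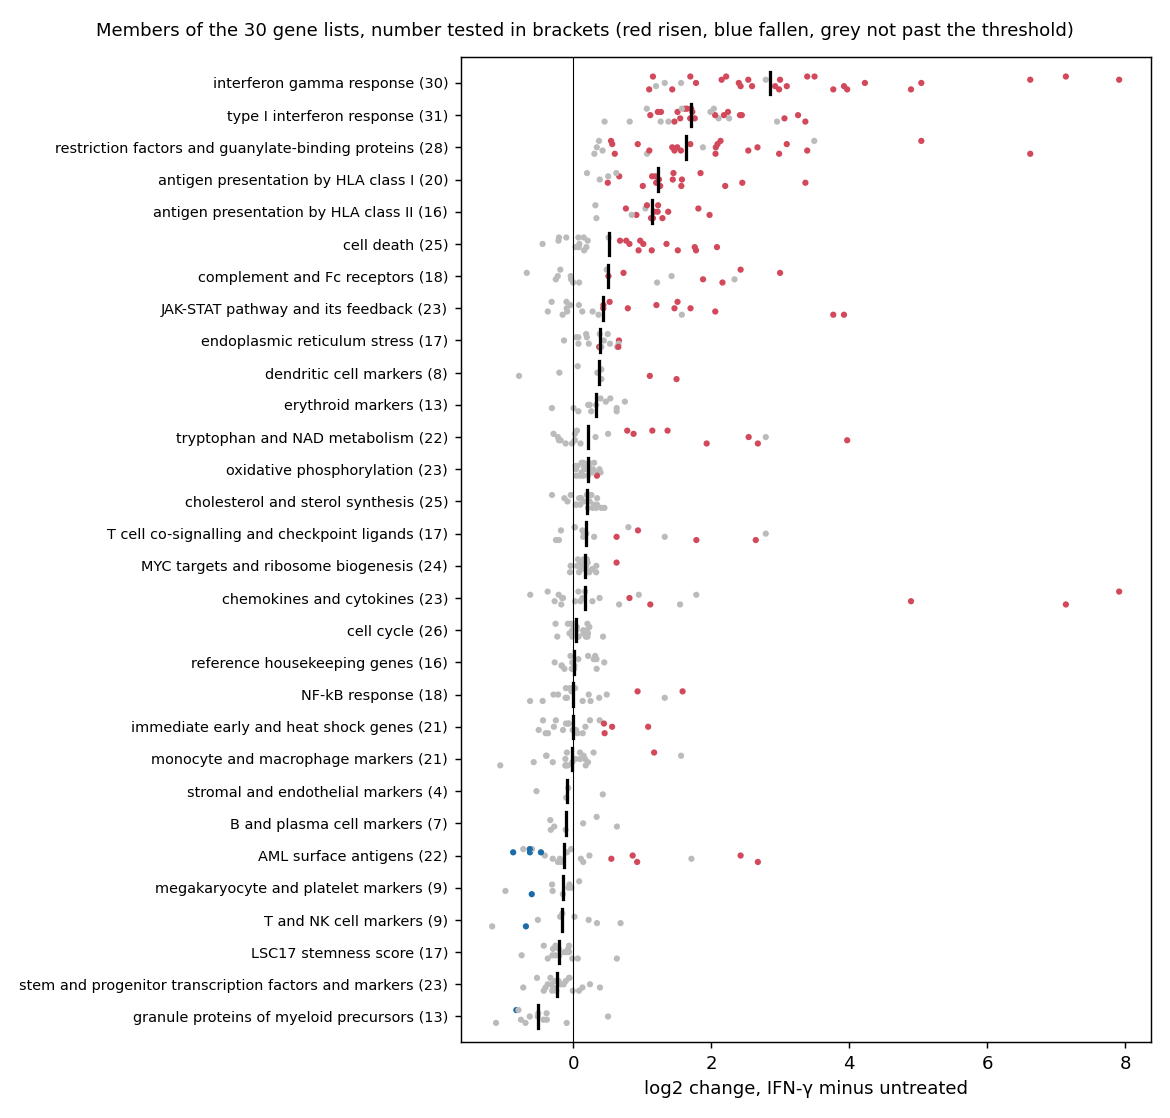
Log2 change with interferon gamma (horizontal axis) of each tested member of the 30 gene lists (rows, ordered by median, with the number tested), with risen members in red, fallen members in blue, other members in grey and the list median as a black bar. Medians run from 2.86 in the interferon gamma response list to -0.51 in the list of granule proteins.

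The third comparison set the donors against each other. Across the 12991 genes, which are not independent replicates, Pearson's r between the log2 changes of 2 donors was 0.63 for A and B, 0.71 for A and C and 0.61 for B and C. Spearman's rho was 0.48, 0.55 and 0.38. Each donor had its own untreated library, so no control was shared. Differences between donors made up 85.1% of the sum of squares of the log2 values, treatment 11.5% and the rest 3.49%.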

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

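The CD38 change stayed positive in every alternative, between 2.33 and 2.82 on the log2 scale, and passed in all but the fit with no replicate block, where it was 2.68 with an adjusted p of 0.999877 (unadjusted limma p of 0.00726). Adjusted p for CD38 ranged from 0.000198 to 0.010005 in the others. Without the block limma called 0 genes, 0 risen and 0 fallen, against 576, 411 and 165 with it, and donor differences hold 85.1% of the sum of squares. Donor as a random replicate block gave 930 genes (668 risen, 262 fallen), of which 510 were among the 576. A pseudocount of 5 gave 360 genes with 74 fallen, and no low filter gave 103 fallen genes. An adjusted p under 0.1 gave 1528 genes (902 risen, 626 fallen), and a minimum change of 1 gave 214 (203 risen, 11 fallen), both by construction. Leaving out each donor gave 263 to 823 genes, 220 to 569 risen and 43 to 254 fallen, with fewer libraries in the fit. Mean agreement between donors was 0.65, was 0.71 with a filter at 5 RPKM, and ranged from 0.61 to 0.71 with 1 donor left out. That range is no separate check, since leaving out a donor leaves a single pair. Quantile normalization gave 59.2% risen among its calls, against 71.4%. Of the 20 lists that passed, camera with an estimated correlation kept 0 and fry kept 4, while fry's mixed test passed 22 of 30 lists. The 4 were the interferon gamma response, restriction factor, JAK-STAT and cell death lists. Type I interferon response genes missed the directional test (fry adjusted p = 0.0674), as did both HLA class lists (0.0591 each). Camera on ranks called 20 lists. The list tests were not run with the random block. Of 77 called genes named by the rule, none changed sign, while 19, 6 and 28 lost the call without donor A, B and C, 20 with a pseudocount of 5, 12 with no filter, and 11 each with quantile normalization and without the trend, 5 with robust eBayes, and 9 with the random block (LGALS9, CD86, FCER1G, CTSG, IL7R, SELP, C1orf186, ELN and MMP2). Among genes named after their values were seen, a pseudocount of 5 also ended the calls of ICOS, HPGDS, CPA3, COL5A1, MMP14 and CLEC12A. CD44 lost its call with the random block (limma adjusted p = 0.0528). Without the trend CD44 (0.0636), CLEC12A (0.0564) and CPA3 (0.0669) lost theirs. The following changed direction in at least 1 alternative, without passing there. The AML antigen list had an adjusted p of 0.279 with no replicate block, 0.702 with fry and 0.440 to 0.959 with a donor left out. The housekeeping list had 0.517 under quantile normalization. With a donor left out, the heat shock list had 0.167 to 0.843, the monocyte list 0.0938 to 0.468, MYC a change of -0.076 to 0.0027 and HDC one of -0.34 to 0.36. HDC was also at -0.10 with a pseudocount of 0.1 and at -0.020 under quantile normalization. The cell cycle list changed direction without donor A (0.226) and passed without donor B, with a range from 1.34e-06 to 0.511 over the donors left out. Where no reason is given the cause was not tested. At these depths genes well under 1 RPKM rest on few reads per library, which limits their changes.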

Other observations

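The 4 gene lists and the genes named here were chosen after their values were seen, and so were the tests described, except the count of sample splits and the test of neighbouring genes. Proteasome genes outside the immunoproteasome moved up together. All 34 tested core and regulatory subunits had a positive change in each of 3 donors, and 12 passed over all genes (33 adjusted over the list alone), with a median of 0.36. PSMA4 rose by 1.02, from 139 ± 47.5 to 286 ± 109 RPKM (SD, n = 3), PSMA2 by 0.90 and PSMB3 by 0.77. The camera adjusted p over the 4 lists was 1.27e-19, against an adjusted p = 0.101 with an estimated correlation.

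Collagens and matrix metalloproteinases, which build and cut the extracellular matrix, moved the other way. Of 37 members 22 were tested, of which 8 fell and 0 rose (13 fell and 1 rose adjusted over the list alone). The median was -0.52 (camera adjusted p = 4.76e-07, against an adjusted p = 0.0879 with an estimated correlation). Besides MMP9 and MMP2, COL6A1 fell by 0.90, MMP14 by 0.74 and COL5A1 by 0.61. Without donor A the calls of COL6A1 (adjusted p = 0.0567) and COL5A1 (0.108) were lost, without donor B that of MMP14 (0.0786), and without donor C those of MMP14 (0.110), COL5A1 (0.144) and MMP2 (0.0908). With donor as a random effect those of MMP14 (0.226), COL5A1 (0.194) and MMP2 (0.0521) were lost. BST1, the closest relative of CD38 and its neighbour on chromosome 4, had a log2 change of -0.20 that did not pass (adjusted p = 0.264).

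CD38 rose by 2.68, and other cells rich in CD38 in the treated libraries are a candidate explanation. The highest change among tested members of the T and NK, B and plasma cell, and monocyte lists was 1.57, in IRF8. It lay under the lower 95% bound of CD38 at 2.27. The list medians were -0.15, -0.11 and -0.01, so the tested markers did not rise as sets. Such cells are not excluded by this, since only 9 of 21 T and NK and 7 of 15 B and plasma cell markers were tested. A marker also need not move as much as CD38. ICOS, TBX21 and the Fc receptor FCGR1A (2.43), which are on none of these lists, lay above the bound of 2.27. SLAMF7, an antigen of NK and plasma cells, was at 1.72 without passing (adjusted p = 0.0537). Rescaling of the libraries by quantiles or medians left CD38 at 2.61 and 2.66, which argues against library scaling as the cause. A response of the CD34-positive cells themselves stays open as a hypothesis.

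The real split of the 6 libraries called 576 genes and was 1 of 10 splits with as many. The highest of the others was 0 with limma (567 or fewer genes at an unadjusted p under 0.05), the 3 others that part all donor pairs included. Those 3 had 90 to 269 genes at an unadjusted limma p under 0.05. Swapping the libraries of a donor puts the treatment effect into the residual, which favours 0 calls, so these splits are no fair measure of chance. Also, 10 splits are too few for a share under 0.05.

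ICOS and TBX21, genes best known from T cells, rose by 2.99 (adjusted p = 0.0124) and 2.68 (adjusted p = 0.00942), from 0.809 ± 0.685 to 15.4 ± 10.1 and from 0.197 ± 0.0986 to 7.42 ± 4.38 RPKM, though with a pseudocount of 5 ICOS was at 1.67 and lost its call (0.0502). More T cell RNA is a candidate explanation. Of the 16 members of the T cell receptor and proximal kinase list 9 were tested, 6 of them also on earlier lists. Of these 0 rose and 1 fell, or 4 fell adjusted over the list alone. The median was -0.41 (camera adjusted p = 0.00585, against an adjusted p = 0.147 with an estimated correlation), and the highest donor median was -0.0073. The tested members thus did not rise as a set. More T cell RNA is not excluded by this, since the tested members are few and the list was chosen after its values were seen. Reads from a neighbouring gene stay open for TBX21 (chromosome 17, 47733244 to 47746119). The sign set beforehand was a rise of 1 or more on the log2 scale in a tested gene within 100 kb. TBKBP1 met it, so that test came out in favour of this explanation. Among 5 tested genes within 100 kb the highest change was 1.46, in TBKBP1 (47694081 to 47712050, same strand), which did not pass (adjusted p = 0.0579) but passed with donor as a random effect (0.0199), with a filter at 5 RPKM (0.0495) and without donor B (0.000567), and ICOS had no tested neighbour. TBKBP1 went from 8.04 to 33.2, 10.7 to 15.5 and 4.35 to 19.8 RPKM in donors A, B and C. TBX21 went from 0.303 to 6.58, 0.107 to 3.52 and 0.182 to 12.2 RPKM. A fixed share of TBKBP1 reads would rise in proportion to TBKBP1, so these values argue against a fixed share. That comparison was made after the values were seen, and untreated TBX21 was near the floor. A share that changes with treatment stays open. Induction within leukaemic cells or within T cells that passed the CD34 selection may also apply and was not tested.

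Mast cell and basophil genes fell in part, with 5 of 18 fallen and 0 risen (12 fallen adjusted over the list alone, 5 of the 18 also on earlier lists) and a median of -0.69 (camera adjusted p = 1.97e-07; adjusted p = 0.0879 with an estimated correlation). CPA3 fell by 0.96, HPGDS by 0.91, TPSB2 by 0.91 (from 320 ± 508 to 203 ± 328 RPKM), TPSAB1 by 0.86 and CTSG by 0.82, though with donor as a random effect each of the 5 calls was lost, CPA3 without donor C (adjusted p = 0.148), and CTSG without donor A (0.0781) or donor C (0.0861). Reads shared between the tryptase copies do not account for it, as the 15 members without them had a median of -0.49. A lower share of mast cells and basophils, mature forms of which the CD34 selection should remove, may apply, but HDC, which such cells express strongly, lay above the median of TPSAB1, TPSB2, CPA3 and HPGDS by 0.92, 1.73 and 0.16 in donors A, B and C (mean 0.94, exact two-sided sign-flip p of 0.25, the smallest 3 donors allow), while HDC was near the floor in donor A and, in donor C, where it was most abundant (84.6 RPKM untreated), changed by -0.59 along with the others. A lower share of these cells and lower expression within them cannot be told apart here, because bulk RNA does not separate the 2. The donors also differ and are few.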
